A study of Picosynechococcus sp. PCC 7002 with 16 samples.

How the data were processed

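Gene expression was measured by RNA sequencing in 16 libraries of Picosynechococcus sp. PCC7002, 4 at each of 0.04%, 4%, 8% and 30% CO2. Per the labels' protocols, cells grew in A+ medium at constant pH 7.5, 30 °C and 250 µmol photons per square metre per second, RNA was extracted with PGTX reagent, and a company removed ribosomal RNA, made the libraries and sequenced them. The deposited table holds whole-number read counts per annotated feature, not normalised. Per the submitters' processing notes, the tools named are fastp 0.2 (read trimming), Bowtie2 2.5.2 (alignment) and featureCounts 2.0.6 (counting). The strand setting, the treatment of reads that map to several places and the genome build are not given in the sources used here, so counts of near-identical copies, overlapping genes and genes opposite one another on the other strand are uncertain. Coordinates are those of the annotation columns of the deposited table, counted from 1.

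The table has 3263 features on 7 replicons, a chromosome and 6 plasmids that hold 379 features. Of these, 3187 are protein-coding, 591 of them annotated as hypothetical, and 662 have a gene symbol. The reference symbol table matched 0 locus tags and was not used, so genes without a symbol are named by tag and product text. The shared prefix SYNPCC7002_ is left out of tags, and tags with RS are of the newer style. The 4 features of 16S and 23S ribosomal RNA have a total count of 0, and 24 features have 0 counts in every library. Totals ran from 12254364 to 23587046 counts per library. Samples were grouped by the CO2 level in their titles, and every sample column was used. Pairs of libraries within a group differed by 7.87 to 146 times counting noise (chi-square per degree of freedom over genes), so no pair looked like a library deposited more than once.

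Genes with enough counts by edgeR's filterByExpr, 3196 in all, were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood models in R 4.3.3 on all 16 libraries, with 1 mean per CO2 level and 12 residual degrees of freedom before moderation. The common biological coefficient of variation was 0.0974. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Comparisons were 30% with 4%, 30% with 8%, 8% with 4% and 0.04% with 4% CO2. The genes changed in both 30% comparisons were counted, as was the overlap of 30% against 8% with 0.04% against 4%. Overlaps were set beside those of independent lists and beside 20 simulations of unchanged groups.

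Before the data were examined, 39 gene lists were defined by words of symbols and products, and 36 had at least 3 measured members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 36 lists. Alternatives were camera with an estimated correlation and fry, whose result tells whether a list's genes move one way on balance and does not compare them with other genes. Off-target members, 25 in all, which the word match took in but which were judged not to belong to their list, were also removed. This check was chosen after the results were seen, and other members found by product text were kept. A further 5 lists, described under the closing observations, were also made after results were seen and were counted, not tested with camera. Counts adjusted over the list alone repeat the Benjamini-Hochberg step within the list.

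Named genes followed a rule fixed before the data were examined. For each comparison it takes up to 10 genes with the largest fitted rise and 10 with the largest fall among annotated genes past the test with a mean of at least 20 CPM and no overlap between the replicates of the compared groups. It also takes up to 4 members with the smallest adjusted p of each list past camera, and a fixed set for carbon uptake, Rubisco, CcmK, nitrogen assimilation, D1, flavodiiron and chaperone genes, identified by product text where the annotation has no symbol. The text gives examples of these. The other stable RNAs (rnpB, ssrS, ffs), ssrA, the candidate small RNA and the members of the 5 later lists were chosen after their values were seen.

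Replicate numbers come from the titles. In 8% against 4% CO2 the deviations of same-numbered libraries from their group means correlated at 0.133 to 0.292 across genes in 4 of 4 pairs, so the numbers were taken to pair these samples and blocked values are given there. Libraries matched their own number best in 3 of these 4 pairs, and equally in 3 of 4 pairs of each 30% comparison. Simulated counts with the means and library sizes of the real libraries and 200 changed genes were used to test the steps, on 3200 genes for each comparison. For 30% against 4% CO2, edgeR recovered 48.0% of 1.25-fold, 90.7% of 1.5-fold, 97.3% of 2-fold and 99.3% of 4-fold changes, and 3.99% of its calls were unchanged genes. For 8% against 4% CO2 it recovered 48.7%, 91.3%, 96.7% and 100%, with 3.28% unchanged. For 30% against 8% CO2 these shares were 47.3%, 90.0%, 98.0% and 99.3%, with 4.33%, and for 0.04% against 4% CO2 44.7%, 90.7%, 98.0% and 100%, with 3.61%. In these simulations smaller changes than 1.5-fold were thus often missed at this depth and replication. Besides the 200 genes, 30 genes of 1 list were changed by 1.25-fold. The data gave 1957, 1978, 29 and 2546 changed genes for 30% against 4%, 30% against 8%, 8% against 4% and 0.04% against 4% CO2. The simulated shares may therefore not carry over to the data.

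Alternatives tried were RLE size factors, scaling by total counts, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of at least 10 CPM in 4 libraries, the replicate number as a block, lane as a covariate, removal of the 10 most abundant genes with ribosomal and transfer RNA, fits on only the compared groups, and each library left out in turn. Fits within a single lane were added after the data were seen. Other splits of the libraries were refitted, 35 for each comparison and 100 drawn for each overlap. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.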

Results

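RNA was sequenced from Picosynechococcus sp. PCC7002, a fast-growing unicellular marine cyanobacterium, grown in A+ medium at 30 °C, pH 7.5 and 250 µmol photons per square metre per second under 4 CO2 levels. The labels call 4% and 8% CO2 optimal and 30% CO2 growth-inhibiting, and 0.04% is the level of air. Each level had 4 replicate libraries, 16 in all, and the values were raw read counts for 3263 annotated features. Total counts were 15054516, 14188687, 13333823 and 14744516 for replicates 1 to 4 at 0.04% CO2, and 15728995, 17973763, 23587046 and 17436155 at 4%. They were 13771967, 12254364, 17628154 and 17977168 at 8%, and 13494364, 18187645, 13126114 and 14456627 at 30%. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be partly technical. Levels are counts scaled by TMM to a common library total (CPM), given as mean ± SD with n = 4, and genes are named by locus tag, where A marks the chromosome and other letters mark plasmids.

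The first principal component of log2 CPM carried 69.8% of the variance and set the 0.04% libraries apart, and the second carried 19.2% and set the 30% libraries apart. The 4% and 8% libraries lay together on both. On the first component the 30% libraries, at 3.72 to 4.62, lay between those at 0.04% (-34.9 or lower) and those at 4% and 8% (16.8 or higher). The transfer-messenger RNA ssrA, which rescues stalled ribosomes, took 21.9% ± 2.37 (SD, n = 4) of all counts at 0.04% CO2, 7.78% ± 0.487 at 4%, 8.35% ± 0.569 at 8% and 16.4% ± 0.628 at 30%. Protein-coding genes took 76.5% ± 2.40, 91.3% ± 0.585, 90.7% ± 0.609 and 81.5% ± 0.650 in the same order.

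**Figure D1:**
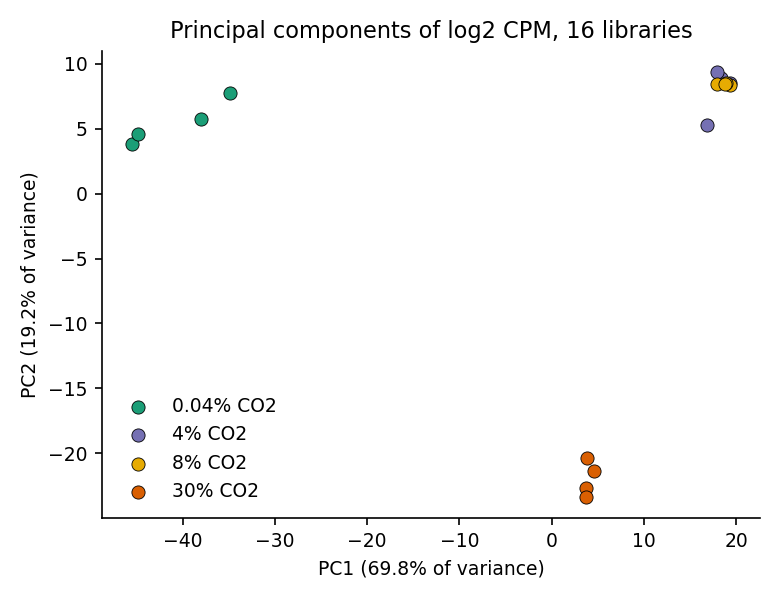
Each point is a library, placed by principal components 1 (69.8% of the variance) and 2 (19.2%) of log2 CPM and coloured by CO2 level. The 4 libraries at 0.04% and the 4 at 30% form separate groups, while those at 4% and 8% lie together.

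The comparison of 30% with 4% CO2 asked which transcripts differ between a growth-inhibiting and an optimal CO2 level. A membrane protease gene and 2 chaperone genes were among the largest rises at 30%, although the list of chaperone and protease genes did not pass as a whole. The site-2 protease family gene A1671 (chromosome 1752547 to 1753677, + strand) reached 1290 ± 85.3 CPM against 123 ± 23.5 at 4% (SD, n = 4), a 10.5-fold difference. The small heat-shock protein gene A0654 (685816 to 686292, - strand) stood at 938 ± 124 against 109 ± 30.4 CPM, 8.59-fold higher, and A2353 (clpB, 2432148 to 2434742, - strand), whose product resolves protein aggregates, at 1218 ± 53.7 against 244 ± 18.3 CPM, 4.999-fold higher. The largest rise among the genes named by the rule was that of A1476, a chlorophyll a/b-binding protein gene (1554767 to 1554976, + strand), at 223 ± 52.6 against 14.4 ± 2.66 CPM, or 15.5-fold. The ammonium transporter gene A2208 (2298334 to 2299863, + strand) fell to 2188 ± 78.6 from 7365 ± 92.2 CPM, 3.37-fold lower at 30%.

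Of the other genes named by the rule, the PIN domain gene F0028 was 11.9-fold higher, the ChaB family gene A0303 11.3-fold, the pentapeptide repeat gene A0244 5.40-fold, the XisI gene F0026 5.16-fold, the histidine kinase gene A0442 5.13-fold and the response regulator gene A0486 4.75-fold. Among the largest falls, the iron uptake porin gene A0782 (808944 to 810554, - strand) stood at 643 ± 16.6 against 3259 ± 673 CPM, 5.07-fold lower. The formate/nitrite transporter gene A0125 was 4.77-fold lower, A0643 (cynS, which encodes cyanase) 4.62-fold and the CHRD domain gene A0568 4.56-fold. The neighbouring ABC transporter genes A1748, A1749 and RS08765 were 3.47-fold, 3.92-fold and 3.54-fold lower. The light-harvesting gene A1292 was 3.43-fold lower and the HEAT repeat gene A1619 3.17-fold. As the rule requires, no replicate value at 30% overlapped one at 4% for any of these 20 genes, and the highest of their edgeR adjusted p values was 3.96e-06.

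Several groups of photosynthesis genes fell at 30% against 4% CO2, with camera's preset correlation of 0.01 between genes. For the lists of this paragraph the estimated correlation was higher, from 0.0768 (ATP synthase) to 0.649 (phycobilisome), so the preset may give p-values that are too small. All 12 genes of the phycobilisome, the light-harvesting antenna of cyanobacteria, were lower, 12 when adjusted over the list alone, with a median log2 fold change of -0.92 (camera adjusted p = 0.000161, and adjusted p = 0.412 with an estimated correlation). Examples were phycocyanin beta A2209 (log2 fold change -1.15), allophycocyanin alpha A1930 (-1.08) and allophycocyanin beta A1929 (-1.04). Of 14 photosystem I genes 11 were lower and 3 did not pass the test, 11 adjusted over the list alone (camera adjusted p = 0.000198, and adjusted p = 0.299 with an estimated correlation). Among them were A1961 (psaA, -0.94) and the subunit II gene A0682 (-0.82). All 5 carboxysome and Rubisco genes were lower, 5 adjusted over the list alone (camera adjusted p = 0.00524, and adjusted p = 0.299 with an estimated correlation). The Rubisco large subunit gene A1798 was at -1.20, the small subunit genes A1796 and A1800 at -1.20 and -0.58, and the CcmK shell protein genes A2612 and A2613 at -0.29 and -0.77, but with scaling by total counts A2612 was at -0.11 and did not pass (edgeR adjusted p = 0.343). Of 25 genes of chlorophyll, heme and bilin synthesis 18 were lower, 2 higher and 5 not past the test, 20 adjusted over the list alone (camera adjusted p = 0.000198, and adjusted p = 0.299 with an estimated correlation). The protochlorophyllide reductase gene A0210 was at -0.96, while bchH A1000 was higher, at 1.60. ATP synthase genes were lower in 10 of 17 cases and not past the test in 7, 10 adjusted over the list alone, atpE A0738 at -0.75 (camera adjusted p = 0.0292, and adjusted p = 0.299 with an estimated correlation). Of 11 genes of carotenoid synthesis and photoprotection 8 were higher, 2 lower and 1 not past the test, the chromosome segregation gene scpB that was taken in by its symbol alone, 10 adjusted over the list alone (camera adjusted p = 0.00524, and adjusted p = 0.299 with an estimated correlation). The high light inducible genes A0602 and RS02630 were at 2.01 and 1.92 and crtD A1623 at 1.96. The same libraries held more tmRNA, 16.4% ± 0.628 of counts at 30% against 7.78% ± 0.487 at 4% (SD, n = 4).

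Ribosomal protein genes fell almost as a block at 30%: of 58 members 55 were lower, 2 did not pass the test and 1 was higher, 56 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 3.33e-13, and adjusted p = 0.299 with an estimated correlation). The member that rose, A0619 (rimO, 0.89), encodes an enzyme that modifies a ribosomal protein; rpsJ A2060 was at -0.93 and rpmI A2181 at -0.89. Of 23 nitrogen assimilation genes 16 were lower and 7 not past the test, 17 adjusted over the list alone (camera adjusted p = 0.000276, and adjusted p = 0.299 with an estimated correlation). The glutamine synthetase III gene A0246 and the nitrate reductase gene A1314 were each at -1.42, and urtA A0398, a urea transporter subunit gene, at -1.55. Glycogen metabolism had 6 of 7 genes lower and 1 not past the test, 6 adjusted over the list alone (camera adjusted p = 0.00521, and adjusted p = 0.194 with an estimated correlation). The phosphorylase gene A0481 was at -0.70 and glgB A1865 at -0.40. Exopolysaccharide and cellulose genes were lower in 23 of 43 cases, higher in 3 and not past the test in 17, 26 adjusted over the list alone (camera adjusted p = 0.00237, and adjusted p = 0.2001 with an estimated correlation). The glycosyltransferase genes A1512 and A1510 were at -1.14 and -1.12, and with scaling by total counts 12 of the 43 were lower and 7 higher, with a median of -0.05 against -0.22. Toxin-antitoxin genes were higher in 23 of 36 cases, lower in 4 and not past the test in 9, 28 adjusted over the list alone (camera adjusted p = 0.00524, and adjusted p = 0.474 with an estimated correlation). The HigB family toxin gene F0023 was at 1.60 and the RelE/ParE family toxin gene E0021 at 0.82.

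Among genes fixed in advance, the bicarbonate permease gene A0470 was lower at 30% than at 4% CO2 by -0.72 on the log2 scale and the CO2 hydration protein genes A0174 and A1807 by -1.10 and -0.62. The list of 4 low-CO2 carbon uptake genes that holds them had 3 lower and 1 higher, 4 adjusted over the list alone, and did not pass (camera adjusted p = 0.0972). The dnaK gene A2418 rose by 0.98, while the dnaK copies A0694 (-0.06) and A2160 (-0.05) did not pass the test and turned positive, 0.11 and 0.12, with scaling by total counts. Both groL genes fell, A0147 by -0.59 and A2458 by -0.85, so the 23 chaperone and protease genes went both ways, with 7 higher, 7 lower and 9 not past the test (camera adjusted p = 0.867), and their median, -0.05, became 0.12 with scaling by total counts. Of the psbA genes, which encode the D1 protein of photosystem II and share near-identical sequence, so that their counts are uncertain, A0157 was at 1.38, A2164 at 1.33 and A1418 at 0.29. A1418 did not pass (edgeR adjusted p = 0.124), but passed with scaling by total counts (0.46) and in a fit of only the compared groups (0.28).

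In total 1957 of 3196 genes tested differed between 30% and 4% CO2 in edgeR, 988 higher and 969 lower at 30%, and 159 of the higher and 100 of the lower ones by at least 2-fold. Scaling by total counts instead of TMM moved the median log2 fold change of all genes by 0.17 and gave 1362 higher and 562 lower. Within lane 1 alone 1874 genes differed and within lane 2 alone 1437, with 1955 and 1957 of the 1957 genes in the same direction. That agreement was largely fixed in advance, since the same libraries gave the calls and 1724 of the 1957 had no overlap between replicate values. Of 36 lists 11 passed camera, 2 higher and 9 lower, and 0 passed with an estimated correlation.

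**Figure D2:**
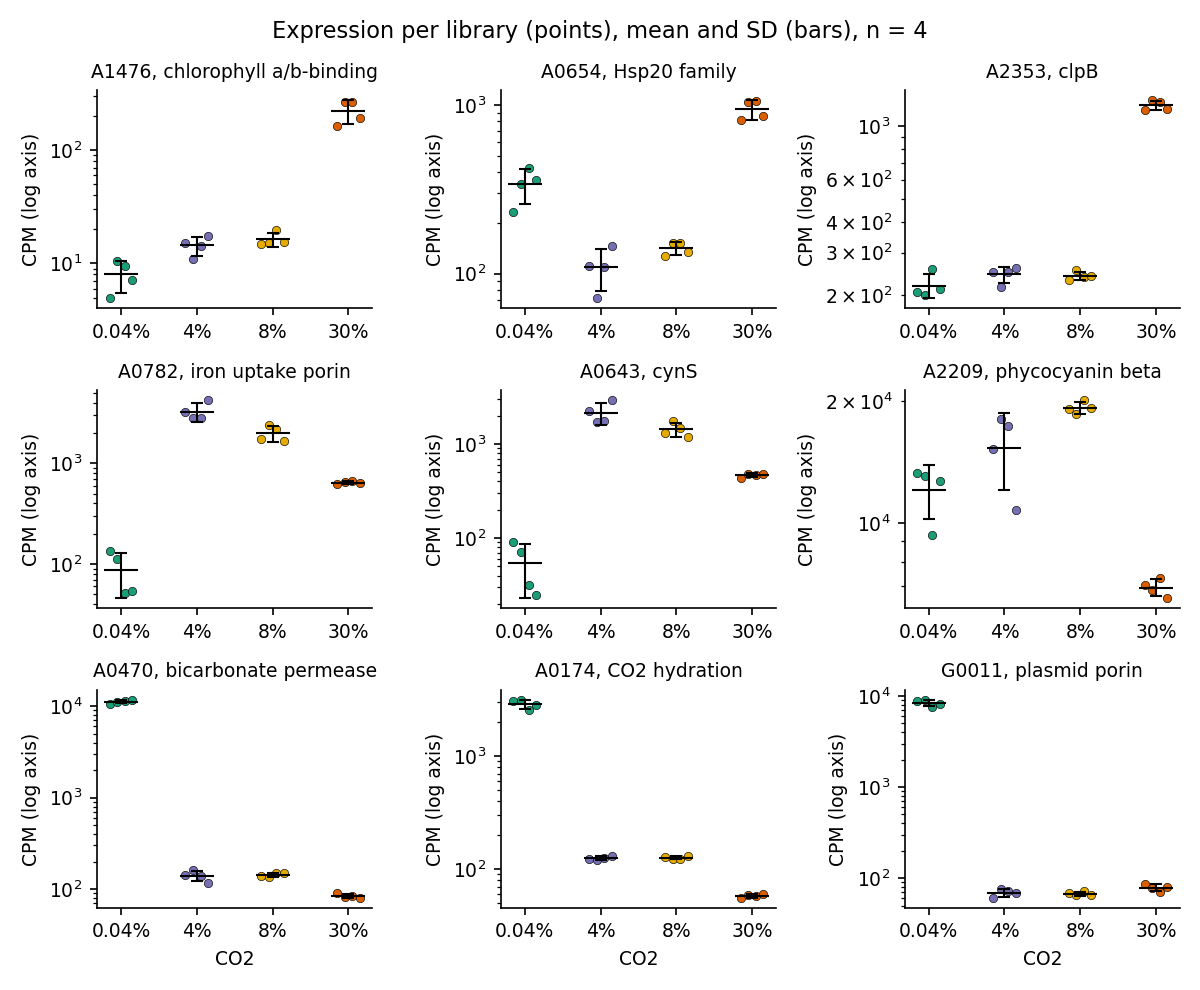
CPM on a log axis for 9 genes at each CO2 level, with 1 point per library and bars for the mean and SD (n = 4). A1476, A0654 and A2353 are highest at 30% CO2, and A0470, A0174 and the plasmid gene G0011 are highest at 0.04%.

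The comparison of 30% with 8% CO2 set the growth-inhibiting level against the other optimal level and shares its 30% libraries with the comparison above. The same protease and chaperone genes were among the largest rises, while their list had 8 of 23 genes higher, 8 lower and 7 not past the test and did not pass (camera adjusted p = 0.932). A1671 was 9.99-fold higher than at 8% (1290 ± 85.3 against 129 ± 7.33 CPM, SD, n = 4), A0654 6.65-fold and clpB A2353 5.06-fold. A1476 was 13.6-fold higher, A0303 11.4-fold, F0028 10.2-fold, A0244 5.98-fold, A0442 4.98-fold, the plasmid methyltransferase gene E0029 4.92-fold and A0486 4.54-fold. The CHRD domain gene A0568 fell most, to 57.4 ± 4.64 from 356 ± 27.1 CPM, 6.19-fold lower, followed by A0423 (hetR, a regulator of heterocyst formation in filamentous relatives), 3.46-fold lower. A2208 and A1292 were each 3.11-fold lower, A0782 and A0643 each 3.09-fold and A0125 2.93-fold. The phycobilisome linker gene A2211 was 2.81-fold, phycocyanin beta A2209 2.78-fold and A0430 (speD) 2.73-fold lower. The highest edgeR adjusted p among these 20 genes was 0.000203.

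All 12 phycobilisome genes were again lower, 12 adjusted over the list alone, with a median of -1.16 (camera adjusted p = 6.98e-06, and adjusted p = 0.304 with an estimated correlation). Photosystem I had 12 of 14 genes lower and 2 not past the test, 12 adjusted over the list alone (camera adjusted p = 3.43e-05, and adjusted p = 0.304 with an estimated correlation), with psaA A1961 at -1.10. Photosystem II, which did not pass against 4%, had 19 of 31 genes lower, 4 higher and 8 not past the test, 23 adjusted over the list alone (camera adjusted p = 0.0373, and adjusted p = 0.589 with an estimated correlation). Its manganese-stabilizing protein gene A0269 was at -1.10 and psbB A1759 at -0.84, and whether the 2 comparisons differ for this list was not tested. With scaling by total counts 9 of the 31 were lower and 10 higher, with a median of -0.11 against -0.36. Genes of chlorophyll, heme and bilin synthesis were lower in 19 of 25 cases, higher in 3 and not past the test in 3, 22 adjusted over the list alone, and all 5 carboxysome and Rubisco genes were lower, 5 adjusted over the list alone, except that A2612 (-0.24) turned to 0.01 with scaling by total counts. These lists had camera adjusted p = 3.43e-05 and 0.00936, and each had adjusted p = 0.304 with an estimated correlation. Ribosomal protein genes were lower in 55 of 58 cases, higher in 1 and not past the test in 2, 56 adjusted over the list alone, with a median of -0.87 (camera adjusted p = 8.2e-16, and adjusted p = 0.304 with an estimated correlation). ATP synthase genes were lower in 10 of 17 cases, higher in 1 and not past the test in 6, and the list did not pass (camera adjusted p = 0.0873).

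Carotenoid and photoprotection genes were higher in 8 of 11 cases, lower in 2 and not past the test in 1, again scpB, 10 adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.304 with an estimated correlation). Genes of 2-component systems were higher in 21 of 53 cases, lower in 7 and not past the test in 25, 27 adjusted over the list alone (camera adjusted p = 0.0478, and adjusted p = 0.304 with an estimated correlation). The kinase gene A0442 was at 2.32 and the regulator gene A0486 at 2.18, and with scaling by total counts 41 of the 53 were higher and 0 lower. This list lost its call with RLE size factors (camera adjusted p = 0.0560). Toxin-antitoxin genes were higher in 21 of 36 cases, lower in 5 and not past the test in 10, 27 adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.478 with an estimated correlation). Nitrogen assimilation genes were lower in 10 of 23 cases and not past the test in 13, 9 adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.478 with an estimated correlation), and with scaling by total counts 6 were lower and 4 higher, with a median of 0.03 against -0.22. Exopolysaccharide and cellulose genes were lower in 22 of 43 cases, higher in 5 and not past the test in 16, 27 adjusted over the list alone (camera adjusted p = 0.00482, and adjusted p = 0.250 with an estimated correlation), and with that scaling 10 were lower and 10 higher, with a median of 0.03 against -0.23. Glycogen metabolism had 6 of 7 genes lower and 1 not past the test, 6 adjusted over the list alone (camera adjusted p = 0.0130, and adjusted p = 0.250 with an estimated correlation). With scaling by total counts 2 of the 7 were lower and 1 higher, with a median of -0.15 against -0.40.

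In total 1978 of 3196 genes differed between 30% and 8% CO2 in edgeR, 1017 higher and 961 lower, and 158 of the higher and 110 of the lower ones by at least 2-fold. Scaling by total counts moved the median log2 fold change of all genes by 0.256 and gave 1636 higher and 442 lower. Within lane 2 alone 1673 genes differed and all 1978 kept their direction, and lane 1 held too few libraries for this comparison. The direction was again largely fixed in advance, with no overlap between replicate values in 1810 of the 1978. Of 36 lists 12 passed camera, 3 higher and 9 lower, and 0 passed with an estimated correlation.

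Genes changed against both optimal levels numbered 1740, 885 higher and 855 lower at 30% CO2, and 0 went in opposite directions. Independent lists would share 314 and 291. Simulations with all 16 libraries drawn from 1 mean per gene shared a mean of 0.05 genes. With nothing changed almost no gene can be called, so this count cannot tell how many genes 2 real responses would share. The log2 fold changes correlated across genes with Pearson's r = 0.955 and covariance 0.346, against 0.506 and 0.00829 in the simulated data. With the 30% libraries divided so that each comparison used 2 of them, the shared genes numbered 1384 to 1424 and the covariance was 0.334 to 0.340. Genes are not independent replicates, so these correlations describe the gene set and carry no p-value.

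The comparison of 8% with 4% CO2 asked whether the optimal levels differ from each other. A few genes for nitrogen acquisition were lower at 8%: the neighbouring genes A0860, A0861 (ntrB, a nitrate transporter permease gene), A0862 and A0863 (cynS, cyanase), at chromosome 888100 to 891853 on the + strand, were 1.94-fold, 1.80-fold, 1.92-fold and 1.89-fold lower. The ammonium transporter gene A2754 stood at 164 ± 20.7 against 302 ± 98.0 CPM (SD, n = 4), 1.85-fold lower, and urtC A0396, a urea transporter gene, was 1.59-fold lower. The ABC transporter genes A1749 and A1748 were 1.75-fold and 1.63-fold lower, and gap A2697 (a glyceraldehyde-3-phosphate dehydrogenase gene) and the Rnf complex gene A1432 were each 1.68-fold lower. Genes higher at 8% were cysT A0797, a sulfate transporter gene, at 90.4 ± 9.30 against 58.2 ± 9.77 CPM, 1.55-fold, with the nearby gene A0799 at 1.40-fold, the fasciclin domain gene A1469 at 1.49-fold and A0568 at 1.36-fold. The highest edgeR adjusted p among these 14 genes was 0.0460. With the replicate number as a block A0396 and A1748 lost the call (edgeR adjusted p = 0.0791 and 0.0556) and the other 12 kept it. Among the 4% libraries replicate 4 was the highest in each of the 8 nitrogen and ABC transporter genes, with A0862 at 97.3, 74.0, 65.8 and 159 CPM in replicates 1 to 4, and without it their log2 fold changes shrank from between -0.67 and -0.95 to between -0.44 and -0.68. A0862 then moved from -0.94 to -0.61 and A1748 from -0.71 to -0.44, and these genes and A0396 lost the call (edgeR adjusted p = 0.160, 0.0852 and 0.182). Only A0568, A2697 and A1432 kept the call whichever library was left out.

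Nitrogen assimilation was lower as a list, with 3 of 23 genes lower and 20 not past the test, 8 adjusted over the list alone, and a median of -0.16 (camera adjusted p = 1.17e-05, 4.48e-05 with the replicate number as a block, and adjusted p = 0.333 with an estimated correlation). The 3 genes were A2754, A0396 and the nitrate reductase gene A1314 (-0.54), of which only A2754 kept its call with the replicate block (edgeR adjusted p = 0.0322, against 0.0791 and 0.0556), and in all 3 replicate 4 was the highest of the 4% libraries. Sulfur assimilation had 1 of 10 genes higher and 9 not past the test, 3 adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.00785, 0.383 with the replicate block, and adjusted p = 0.333 with an estimated correlation). Hydrogenase and fermentation had 1 of 12 genes lower, nifJ A1443 at -0.67, and 11 not past the test, 3 adjusted over the list alone (camera adjusted p = 0.00557, 0.0504 with the replicate block, and adjusted p = 0.333 with an estimated correlation). Of 58 ribosomal protein genes 0 passed the test, and 0 did so adjusted over the list alone, with a median of 0.14 (camera adjusted p = 1.03e-07, 0.650 with the replicate block, and adjusted p = 0.404 with an estimated correlation). Likewise 0 of 12 phycobilisome genes and 0 of 31 photosystem II genes passed, 0 and 0 adjusted over the list alone, with medians of 0.23 and 0.15. Camera gave these lists adjusted p = 1.17e-05 and 1.15e-05, 0.184 and 0.0504 with the replicate block, and adjusted p = 0.333 with an estimated correlation for both. With scaling by total counts the medians of the ribosomal protein, phycobilisome, photosystem II and sulfur lists moved towards 0, to 0.06, 0.15, 0.08 and 0.02, and that of nitrogen assimilation away from it, to -0.25. Photosystem I, cytochrome b6f and chlorophyll synthesis, higher, and the list of pentose phosphate and glycolysis genes, lower and without gap, also passed camera with 0 members past the gene test, 0, 0, 1 and 0 adjusted over the list alone, and lost the call with the replicate block (camera adjusted p = 0.3155, 0.1004, 0.286 and 0.1004). With an estimated correlation camera gave them adjusted p = 0.394, 0.333, 0.333 and 0.333.

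In total 29 of 3196 genes differed between 8% and 4% CO2 in edgeR, 7 higher and 22 lower, and 417 had an unadjusted p under 0.05. At 2-fold or more edgeR called 0 genes, with 3 at an unadjusted p under 0.05, and DESeq2 called 1. Scaling by total counts gave 3 higher and 37 lower. The count depended on single libraries and on the tool: it was 5 without 8% replicate 1, 7 without 8% replicate 4, 13 without 8% replicate 3, 17 without 4% replicate 4 and 55 without 4% replicate 2, and DESeq2 called 94. Within lane 2 alone 61 genes differed, 20 of them among the 29. All 29 kept their direction, but this was fixed in advance. The lane 2 libraries had also given the calls, and no replicate values of the 2 levels overlapped in any of the 29.

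The comparison of 0.04% with 4% CO2 set air against an optimal level. The sodium-dependent bicarbonate permease gene A0470 (chromosome 501262 to 502374, - strand) stood at 11223 ± 442 against 140 ± 18.1 CPM (SD, n = 4), 80.4-fold higher. A cluster of 5 genes at 178297 to 184550 on the + strand rose with it, with the LysR regulator gene A0171 26.1-fold, the NADH dehydrogenase subunit genes A0172 and A0173 26.8-fold and 24.5-fold, the CO2 hydration protein gene A0174 23.1-fold and the fasciclin domain gene A0175 23.9-fold higher. The largest rise among the genes named by the rule was that of the plasmid iron uptake porin gene G0011 (12511 to 14241, - strand), at 8391 ± 672 against 69.3 ± 6.53 CPM, or 121-fold. Among the largest falls, A0643 (cynS) was 39.3-fold lower, A1313, an MFS transporter gene, 33.0-fold, A0125, the formate/nitrite transporter gene, 25.01-fold, A1314, nitrate reductase, 24.3-fold and A1827, nitrite reductase, 16.2-fold. The chromosomal iron uptake porin gene A0782 stood at 87.8 ± 42.0 against 3259 ± 673 CPM, 37.0-fold lower.

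Another 3 genes rose about as much as the CO2 hydration cluster, namely A2493 (a nitrogenase C-terminal domain gene) 21.2-fold, A1732 (Sua5 family) 20.4-fold and the SulP anion transporter gene A2371 19.7-fold. The sulfate-binding protein gene A0795 was 16.5-fold lower, A1619 13.8-fold, the RlpA family gene A0344 12.98-fold and the SLC13 permease gene A0794 11.2-fold. The highest edgeR adjusted p among these 20 genes was 2.54e-10. The diflavin flavoprotein genes A1321 and A1743, of the family that passes electrons to oxygen, rose by 2.96 and 3.09 on the log2 scale. The psbA genes A0157, A1418 and A2164, uncertain as near-identical copies, rose by 1.38, 1.75 and 2.26, the Hsp20 gene A0654 by 1.63 and glnA A1630 by 0.64. Both groL genes fell, A0147 by -0.92 and A2458 by -1.37.

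Of 58 ribosomal protein genes 55 were lower at 0.04% than at 4% CO2, 1 was higher and 2 did not pass, 56 adjusted over the list alone (camera adjusted p = 5.74e-13, and adjusted p = 0.440 with an estimated correlation). Their median was -1.41, with rpsB A1959 at -2.60 and rplA A1028 at -2.31, and the member that rose, rimI A0096 (0.24), encodes an enzyme that modifies a ribosomal protein. Carboxysome and Rubisco genes fell in 5 of 5 cases, 5 adjusted over the list alone (camera adjusted p = 0.0261, and adjusted p = 0.440 with an estimated correlation). A1798 was at -0.70, A1796 at -1.09, A1800 at -1.35, A2612 at -1.18 and A2613 at -1.21. Genes of the NDH-1 complex, a proton-pumping dehydrogenase of thylakoids, were higher in 13 of 16 cases and lower in 3, 16 adjusted over the list alone (camera adjusted p = 0.00926, and adjusted p = 0.440 with an estimated correlation). The subunit genes A0172, A1143 and A1973 were at 4.74, 2.20 and 2.00. Nitrogen assimilation genes were lower in 15 of 23 cases, higher in 3 and not past the test in 5, 18 adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.440 with an estimated correlation). Sulfur assimilation had 8 of 10 genes lower and 2 not past the test, 8 adjusted over the list alone (camera adjusted p = 0.0213, and adjusted p = 0.440 with an estimated correlation). The genes cysT A0797 and cysC A1494 were at -3.20 and -2.46. Fatty acid and lipid synthesis had 17 of 24 genes lower, 4 higher and 3 not past the test, 21 adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.440 with an estimated correlation). The desaturase gene A0159 was at -1.96.

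Toxin-antitoxin genes were higher at 0.04% CO2 in 22 of 36 cases, lower in 3 and not past the test in 11, 25 adjusted over the list alone (camera adjusted p = 0.0136), and with scaling by total counts 17 were higher and 5 lower, with a median of 0.21 against 0.44. Exopolysaccharide and cellulose genes were lower in 26 of 43 cases, higher in 10 and not past the test in 7, 36 adjusted over the list alone (camera adjusted p = 0.0419). Both lists had adjusted p = 0.440 with an estimated correlation. The 4 low-CO2 carbon uptake genes did not pass as a list (camera adjusted p = 0.115), with 3 higher and 1 lower, 4 adjusted over the list alone, and a median of 2.44. The list holds A0470 and A0174 but not A0172, A0173 or A2371, which rose strongly as given above, so its test does not speak for those genes. Photosystem I had 6 of 14 genes higher, 2 lower and 6 not past the test, and the list did not pass (camera adjusted p = 0.336), with a median of 0.20 that became -0.02 with scaling by total counts. In these libraries tmRNA took 21.9% ± 2.37 of counts at 0.04% against 7.78% ± 0.487 at 4% (SD, n = 4).

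In total 2546 of 3196 genes differed between 0.04% and 4% CO2 in edgeR, 1272 higher and 1274 lower, and 414 of the higher and 406 of the lower ones by at least 2-fold. Scaling by total counts moved the median log2 fold change of all genes by -0.22 and gave 946 higher and 1562 lower. Within lane 2 alone 2331 genes differed, and 2541 of the 2545 genes tested there kept their direction, while lane 1 held too few libraries. Here too the direction was largely fixed in advance, with no overlap between replicate values in 2246 of the 2546. Of 36 lists 8 passed camera, 2 higher and 6 lower, and 0 passed with an estimated correlation.

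**Figure D3:**
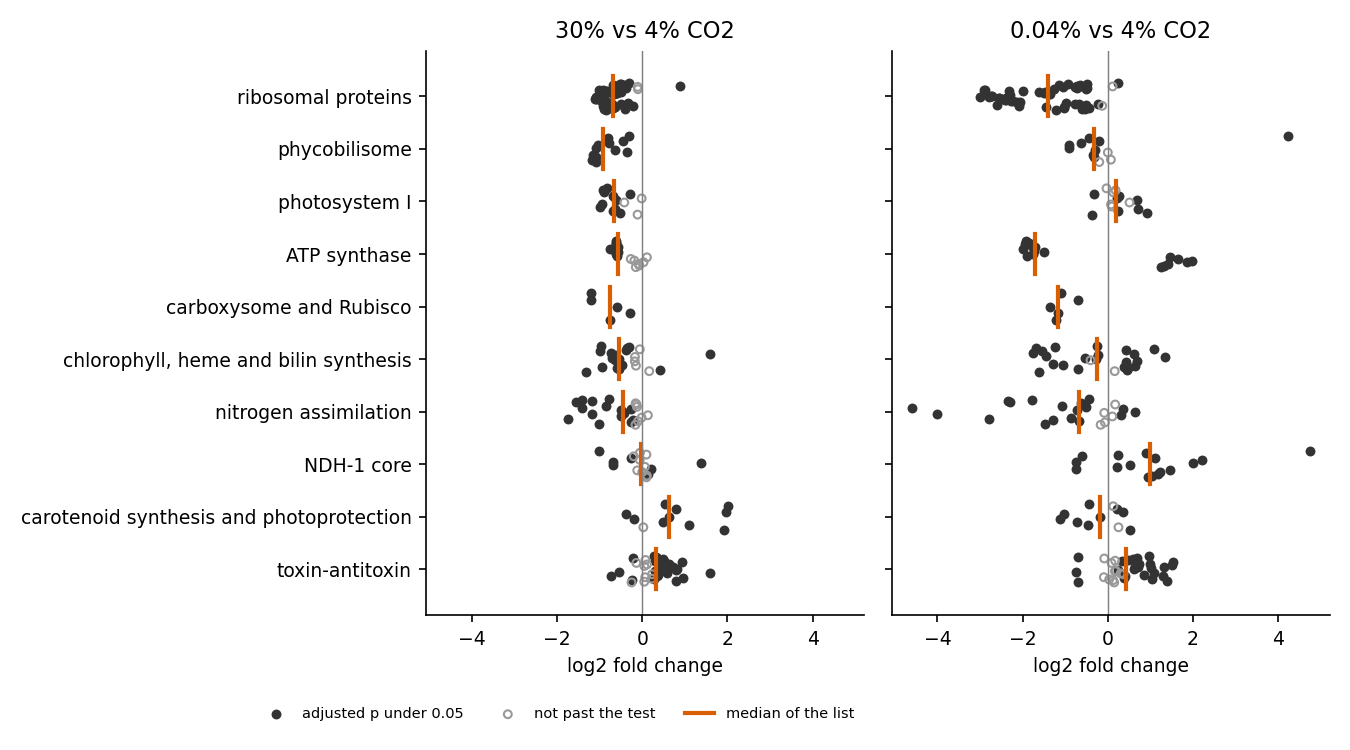
Log2 fold changes of the members of 10 gene lists at 30% against 4% CO2 (left) and 0.04% against 4% CO2 (right), with filled points past the edgeR test and lines at the list medians. The ribosomal protein medians are -0.70 and -1.41, and the photosystem I medians are -0.67 and 0.20, the latter -0.02 with scaling by total counts.

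The last comparison asked whether the same genes differ at the lowest and at the highest CO2 level, using 30% against 8% and 0.04% against 4%, which share no library. Of 3196 genes 673 were higher in both and 682 lower in both, and 305 went in opposite directions. Independent lists would give 405, 383 and 788, and Fisher's exact test over genes, which treats genes as independent, gave p = 8.2e-96 for the higher and p = 8.82e-123 for the lower ones. Ribosomal protein genes made up 54 of those lower in both, from a list of 58, and ATP synthase 10 of 17, phycobilisome 8 of 12 and carboxysome and Rubisco 5 of 5. Toxin-antitoxin genes were higher in both in 16 of 36 cases. Photosystem I and NDH-1 each had 5 genes lower at 30% and higher at 0.04%, but with scaling by total counts only 3 photosystem I genes were higher at 0.04% and only 3 NDH-1 genes lower at 30%. Across genes the log2 fold changes correlated with Pearson's r = 0.458 and Spearman's rho = 0.545, with covariance 0.291, against a covariance of 0.000212 and a highest r of 0.0794 in 20 simulations with no change.

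**Figure D4:**
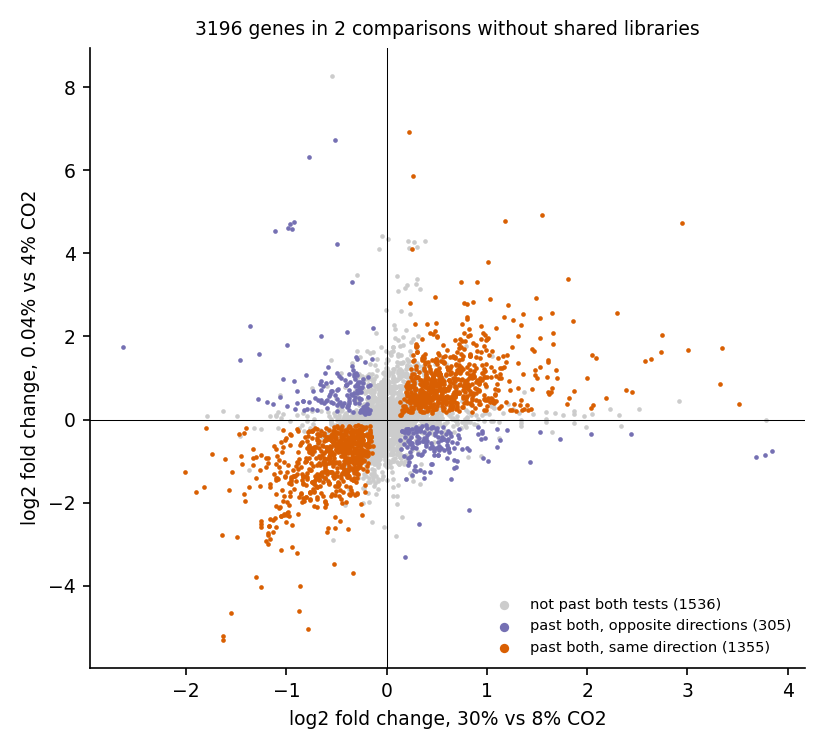
Each point is a gene, placed by its log2 fold change at 30% against 8% CO2 and at 0.04% against 4% CO2. The 1355 genes past both edgeR tests in the same direction outnumber the 305 in opposite directions.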

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

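Each set of 4 replicate values of the genes named in the text and of the library shares was tested for a single value far from the other 3 with Dixon's test. Of 480 sets 29 had such a value, and chance alone gives about 1 in 20. The rule was fixed before the data were examined, while the genes it was applied to include some chosen after results were seen. All libraries were kept.

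In 4% replicate 4, with 9 such values, the most of any library, urtA A0398 stood at 5397 CPM (others 4094 to 4172), nitrite reductase A1827 at 7025 (5310 to 5503), glnA A1630 at 141 (98.4 to 104) and glgB A1865 at 707 (638 to 644). In the same library crtD A1623 stood at 11.9 (8.91 to 9.16), A0694 at 289 (278 to 279), A0096 at 29.0 (24.2 to 24.7), cysC A1494 at 520 (632 to 643) and rpmI A2181 at 632 (781 to 803). The cause was not tested. Leaving this library out gave 17 genes between 8% and 4% CO2 against 29.

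At 4% CO2 the others were ssrA A0032 at 82133 CPM in replicate 1 (73304 to 74203), A0795 at 94.2 in replicate 2 (123 to 129) and F0023 at 25.9 in replicate 3 (20.3 to 20.98). At 8% CO2 F0023 stood at 27.2 in replicate 1 (22.7 to 23.2), A1494 at 646 (688 to 695) and A1630 at 102 (78.0 to 81.5) in replicate 2, and A1476 at 19.7 (14.96 to 15.5) and A2164 at 17.7 (26.0 to 27.2) in replicate 3.

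At 0.04% CO2 replicate 1 had A0186 at 245 CPM (360 to 366), A0486 at 35.6 (42.0 to 42.7), A2160 at 248 (228 to 230) and A2612 at 30.6 (23.6 to 24.6). Replicate 3 had the photosystem I gene A0682 at 3479 (3712 to 3752) and phycocyanin beta A2209 at 9349 (12660 to 13238), and replicate 4 the candidate PsrR1 RNA at 3.00 (0.665 to 0.985). At 30% CO2 A1973 stood at 1114 in replicate 1 (1038 to 1045), RS16875 at 0.613 in replicate 2 (1.15 to 1.18), and RS16880 at 5.32 (1.95 to 2.43) and ssrA at 155321 (136619 to 139334) in replicate 3. RNase P RNA took 1.97% of counts in replicate 4 (1.68% to 1.70%).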

How the results depend on the processing

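The fits within a single lane and the removal of off-target members were chosen after the results were seen. The count for 8% against 4% CO2 was the least stable. It was 29 in edgeR, 94 with DESeq2, where 62 genes had no adjusted p, and 61 within lane 2, and leaving out each library in turn gave 5 to 55, with 5 without 8% replicate 1, 7 without 8% replicate 4, 13 without 8% replicate 3, 17 without 4% replicate 4 and 55 without 4% replicate 2. Other settings gave 27 (RLE), 40 (total counts), 38 (lane), 24 (replicate block, 22 of them shared) and 32 (only the compared groups). The cause was not tested. Leaving out libraries gave 1813 to 1947 genes for 30% against 4%, 1842 to 1902 for 30% against 8%, 2475 to 2527 for 0.04% against 4%, 1604 to 1769 changed in both 30% comparisons and 1271 to 1384 in the overlap.

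With the replicate number as a block the counts were 1990 (30% against 4%), 1996 (30% against 8%), 2564 (0.04% against 4%), 1371 (overlap of 30% vs 8% and 0.04% vs 4%) and 1763 (genes changed both 30% vs 4% and 30% vs 8%). Only in 8% against 4% did all 4 pairs of same-numbered libraries correlate over 0.1, the limit set for pairing, though 3 of 4 did so in 30% against 8% and 2 of 4 in 30% against 4%. Outside 8% against 4% the correlations of same-numbered libraries ran from 0.0456 to 0.254, 0.0215 to 0.428 and -0.184 to 0.0713. The block left 1 of the 10 lists past camera in 8% against 4%, nitrogen assimilation. With an estimated correlation 0 lists passed in each of the 4 comparisons. Fry called 27, 31, 0 and 34 of 36 lists for 30% against 4%, 30% against 8%, 8% against 4% and 0.04% against 4% CO2. Removing off-target members gave 12, 13, 10 and 8 lists past camera, against 11, 12, 10 and 8 with them. The added list was cell division. Its camera adjusted p went from 0.963 to 0.0214 in 30% against 4% and from 0.932 to 0.0352 in 30% against 8% CO2.

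Among the alternative counts 16 moved by more than 1.5 times. Of named genes 76 of 84 kept direction and call under all alternatives for 30% against 4%, 74 of 84 for 30% against 8%, 41 of 76 for 8% against 4% and 64 of 67 for 0.04% against 4%. The CcmK gene A2612 (gene A2612 30% vs 8%) was the only named gene past the test that changed sign, 0.014 with total counts against -0.24, and total counts lack the composition correction of TMM. Genes not past the test changed sign too, among them A0694 and A2160, at 0.11 and 0.12 in 30% against 4% and, past the test with total counts, at 0.21 and 0.22 in 30% against 8% CO2.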

Other observations

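The lists in this part, the RNAs and the single genes named were chosen after their values were seen. Of 13 cation:proton antiporter genes found by product text 9 were higher and 4 lower at 0.04% than at 4% CO2, while of 6 genes in the antiport list fixed in advance 3 were higher, 1 lower and 2 not past the test, and that list did not pass (camera adjusted p = 0.471). Of the 9, 7 lie together at chromosome 2454712 to 2461619 on the + strand next to the SulP transporter gene A2371, among them A2372 at a log2 fold change of 4.28, A2373 at 4.30, A2374 at 4.12 and A2380 at 3.38. At 30% against 4% CO2 2 of the 13 were higher and 3 lower. The 4 high light inducible and chlorophyll a/b-binding protein genes were all higher at 30% than at 4% CO2 (A1476 3.95, A0602 2.01, RS02630 1.92, A0186 1.76), while at 0.04% 2 were higher, 1 lower and 1 did not pass. The phycobilisome linker gene A0639 was at 4.24 at 0.04% CO2, while 8 of the 12 phycobilisome genes were lower.

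By product text, 11 carboxysome genes could be found, and 10 were lower and 1 higher in 30% against 4% as in 0.04% against 4% CO2. The exception, A2389, was at 0.79 and 1.89. Of 10 genes for nitrate, nitrite, cyanate and P-II proteins 7 were lower at 30% than at 4% CO2, and at 0.04% 7 were lower and 3 higher. A neighbouring group of a cyclase, a heme oxygenase, a coproporphyrinogen oxidase and a desaturase gene had 3 of 4 members lower at 30% than at 4% CO2, and 2 higher, 1 lower and 1 not past the test at 0.04%. ATP synthase genes divided at 0.04% CO2 into 7 higher and 10 lower.

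Among stable RNAs, RNase P RNA rnpB was at 1.05 at 30% against 4% CO2 and at 1.18 at 0.04%, 6S RNA ssrS at 0.59 and 0.18 and the signal recognition particle RNA ffs at 1.005 and 1.28. The value for ssrS at 0.04% did not pass the edgeR test (adjusted p = 0.273). That for ffs at 30%, with 37.7 to 139 CPM in the 4 libraries, fell to 0.54 without 30% replicate 3 and also lost its call without 30% replicate 1, 4% replicate 3 or 4% replicate 4 (0.93, 0.96 and 0.91). The tRNA-OTHER features RS16870, RS16875 and RS16880 were at 4.73, 4.78 and 4.92 at 0.04% against 4% CO2, with means of 10.3, 11.5 and 16.9 CPM at 0.04% and 0.388, 0.428 and 0.556 CPM at 4%. A feature annotated as a candidate PsrR1 small RNA (Candidate_RF02701_PsrR1) was at 2.92 at 30% against 4% CO2, with 8.53 ± 7.70 against 1.09 ± 0.151 CPM (SD, n = 4), and its 30% values were 5.81, 5.85, 19.9 and 2.60 CPM, with replicate 3 the highest.

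The share of tmRNA at both extreme CO2 levels was weighed against the yield of short RNAs and against lane, with both tests chosen after the result was seen. If extraction had favoured all stable short RNAs, the other 31 should have risen like ssrA, which was at 1.72 (SE 0.11) at 0.04% and 0.91 at 30% CO2. Their median was 0.54 (SD 1.64) at 0.04% and 0.30 (SD 0.82) at 30%, a spread too wide to tell whether yield could account for part of the rise. Within a lane ssrA stayed at 1.79 or more at 0.04% and at 0.90 or more at 30% CO2, so a lane difference was excluded. A narrower yield test on rnpB, ssrS and ffs alone, with another decision rule, was tried later and favoured yield at 30%, where rnpB and ffs lay above ssrA but ssrS (0.59) below, as did ffs (0.54) without 30% replicate 3, and could not tell at 0.04%, where all 3 lay below ssrA, so yield is left open.

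The genes that moved alike at 30% against 8% and at 0.04% against 4% CO2, with r = 0.458, were weighed against scaling by abundant RNAs (chosen after the result was seen), a feature length trend and the ribosomal protein genes. Removing the abundant and stable RNAs moved all genes by nearly the same amount (SD of the move 0.00043 and 0.00053), and r was 0.453. Such a common shift can neither create nor remove r, so this scaling does not account for r. The count of shared genes does depend on scaling: with total counts the shared genes (overlap of 30% vs 8% and 0.04% vs 4%) numbered 1092. The length trend carried 0.870% and 2.30% of the variance, and r was 0.454 with it removed and 0.433 without the ribosomal protein list, so neither accounts for it. Among 100 splits of the same libraries 1, the real one with 1355 shared genes, gave as many, and the highest other gave 0. Splits of either comparison alone, other than the real one, gave 0 changed genes, so no shared genes could arise. These splits therefore cannot tell whether real responses in both comparisons share more genes than chance. The same limit holds for the 1740 genes changed in both 30% comparisons, 1 of 100 splits with the highest other at 0.

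The differences between 8% and 4% CO2 were weighed against 4% replicate 4 and against lane, with both tests chosen after the result was seen. Without 4% replicate 4 the fold changes of the 29 genes kept a median ratio of 0.890 (SD 0.17) to those with it. With lane in the model 29 stayed called, so neither alone accounts for the 29 genes as a set. A part due to replicate 4 stays open, since without it the named genes A0862, A1748, A0396, A1314 and A0799 lost the call (edgeR adjusted p = 0.160, 0.0852, 0.182, 0.110 and 0.0518). Of 35 splits 2, the real one with 29 genes included, gave as many, and the highest other, 41, put replicates 1 and 4 of both levels against 2 and 3, so by that count chance was not excluded. The 8 splits that part all 4 numbered pairs, where the highest other gave 0 genes, were too few for a share under 0.05.

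For the other comparisons the real split was the only 1 of 35 with as many changed genes, 1957 for 30% against 4%, 1978 for 30% against 8% and 2546 for 0.04% against 4% CO2, and the highest other gave 0. The real split was thus the most extreme, with a share under 0.05, and 1 of 35 is the smallest share this test can give. The other splits mix levels that differ in many genes, which widens the spread within their parts and holds down their counts. A chance difference between cultures was not excluded, since the labels do not say whether replicates were separate cultures. For the number of lists past camera these splits did not exclude chance, and many of them cannot measure it. A split that exchanges 1 library between levels keeps part of the CO2 difference, which can itself move lists. As many lists passed in 4 of 35 splits for 30% against 4% (11 lists, highest other 12) and 2 for 30% against 8% (12, highest other 12). It was 3 for 8% against 4% (10, highest other 10) and 5 for 0.04% against 4% (8, highest other 11). Outside 0.04% against 4%, every other split with as many lists exchanged 1 library. At 0.04% against 4% a split with 2 libraries of each level on either side also gave 11 lists.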
